A study of Homo sapiens with 10 samples.

How the data were processed

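Total RNA of cell suspensions made by digesting colon biopsies was sequenced in bulk, in 5 donors with inflammatory bowel disease (IBD) of the whole colon and in 5 donors without IBD. Each donor gave 1 library, and the 2 groups are separate donors. The libraries were sequenced in pairs of short Illumina reads. The submitters' processing notes name CASAVA 1.8.2, STAR 2.3.0 and DESeq2 1.38.3. The role of each tool, the genome build, the annotation, the counting tool and the strand setting are not given in the sources used here, so no coordinates are printed and reads of a gene and of an overlapping antisense gene cannot be separated.

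The deposited table holds 25702 genes by Entrez number in 10 columns, and its values are a signal: read counts per gene that the authors divided by a size factor for each library. Dividing each column by its smallest step gave whole reads for 100% of the values at a tolerance of 0.001. The recovered depth was 33.9 to 74.1 M reads per library. DESeq2 size factors recomputed on these 10 libraries were 1.06 to 1.13 times the deposited ones, so the deposited factors were not exactly those of this set of genes and libraries. A row of group names inside the table matched the group labels in 10 of 10 columns. Replicates are numbered in accession order only. No paired analysis was possible because these numbers tie no donor of one group to a donor of the other. Within the groups, all 20 pairs of libraries differed far beyond counting noise, with a chi-square of at least 188 per degree of freedom, and Spearman correlations across genes of 0.915 to 0.982, so no library was counted as a copy of another.

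Before any test, 120 genes were removed: the Y-linked block of the table, XIST and TSIX. CD24 stood inside that block and was removed with it. Of the 25702 genes, 1932 had no symbol in the table. The reference gene table gave a symbol for 2 of these through the Entrez number, and the other 1930 were tested and are not named. Of the 25582 genes left, 2043 had no read in any library. Symbols are those of the table, with mitochondrial genes under their MT- names.

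The main test was limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend) on log2(value + 1), two-sided, with no further scaling and no covariate, over genes with a mean of at least 10. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are IBD minus control on this log2 scale with their standard error (SE), which understates the change of genes with low values. Levels are mean normalised read counts ± SD over the 5 libraries of a group. Where a group had no read, the fold was bounded by 3 reads over the whole group. Such floors cover counting error only, since the reads carry no molecular identifiers.

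Gene lists for 33 pathways and cell types were fixed before the data were examined, as were the test, the rule for naming genes and the first set of alternative settings. Lists were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and needed at least 5 tested members. Beside it stand camera with a correlation estimated for each list and fry. Lists are described as higher or lower by the preset test. The preset lies below the correlation estimated for most lists, so its adjusted p can be too small. The lists mark cell types in bulk RNA and count no cells. Named genes are the 12 largest rises and the 12 largest falls among called genes whose higher group mean is at least 50, up to 4 members with the smallest p in each list, and 15 genes of type 2 immunity, eosinophils, bile acids and fatty acid receptors named whatever their result. Immunoglobulin and T cell receptor variable segments, genes with common copy number variants, most classical HLA genes, pseudogenes and clone names were never named. Gene families in the closing section were scanned by the stem of the symbol, with at least 8 tested members, Fisher's exact test and adjustment over both directions of 279 families.

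The alternatives chosen at that point were pseudocounts of 0.5 and 5, no filter, a minimum mean of 50, TMM factors, equal column totals, quantile normalisation, array weights, the mean of the pan-epithelial list as a covariate, edgeR 4.0.16 quasi-likelihood and DESeq2 1.42.0 on the recovered reads, and leaving out each library in turn. Another 4 alternatives were added after the data were seen. The size factors fell into 2 classes with nothing between 0.680 and 1.17, so the class was added as a covariate and each class was tested alone. A further alternative left out the libraries with more than 25% of reads from mitochondrial rRNA, control replicate 1 and IBD replicate 2. Exact permutation tests of single measures enumerate all divisions into 5 and 5, whose smallest two-sided p is 0.00794. Of the 126 divisions of the libraries, 100 were drawn and refitted. Tables and figures used Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

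The procedure was tested on simulated data built from these libraries, with 200 genes changed. It recovered 10.0% of genes changed 2-fold and 63.0% of genes changed 4-fold, and 7.59% of its calls were unchanged genes. In the data 3632 of 18235 genes were called. With so few changed genes the adjusted threshold in the simulation is stricter, so its recovery is not the sensitivity of the data. Both lists that were seeded with a change were called, and 0 of the 31 others. The simulated genes varied independently, while members of real lists vary together (estimated correlation 0.947 for the mitochondrially encoded transcripts). The simulation therefore does not test list calls under such correlation.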

Results

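Gene expression was measured by bulk RNA sequencing of digested colon biopsies from 5 donors with pan-colitic IBD, an inflammation that involves the whole colon, and 5 controls without IBD. Depth was 57.5 ± 17.1 M reads in controls and 51.1 ± 13 M reads in IBD (mean ± SD, n = 5 each; exact permutation p = 0.50). Mitochondrial rRNA took 15.4% ± 9.48 of reads in controls and 12.3% ± 9.47 in IBD, with 28.3% in control replicate 1 and 27.5% in IBD replicate 2. Mitochondrial mRNA took 9.02% ± 4.45 in controls and 3.56% ± 2.17 in IBD (exact permutation p = 0.0238, adjusted p = 0.190 over 8 library measures). Immunoglobulin genes took 2.66% ± 3.18 in controls and 10.3% ± 6.97 in IBD (exact permutation p = 0.0635, adjusted p = 0.254). Size factors were 1.17 to 1.71 in 5 libraries (3 controls and 2 IBD) and 0.556 to 0.680 in the other 5 (2 controls and 3 IBD). The labels give no cause for these 2 classes.

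The comparison of IBD with control colon asked which genes differ in the inflamed human colon. On the log2(value + 1) scale the largest rise was in SERPINB7 and the largest fall in CLDN8. By the ratio of group means RIMS4 (121-fold), SLC6A19 (104-fold) and DPP10 (79.3-fold) fell further than CLDN8 (72.2-fold). Of 18235 genes tested, 3632 (19.9%) changed, with 1901 higher and 1731 lower in IBD (limma, adjusted p under the threshold). A change of at least 2-fold was seen for 1366 of the higher and 1065 of the lower genes. A change of at least 16-fold was seen for 129 and 62. Among all tested genes, 2703 (14.8%) had no overlap between IBD and control libraries, against 0.794% expected by chance.

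The 12 largest rises included 3 protease inhibitors of the serpin family, known from squamous epithelium, without a single read in the controls. SERPINB7 (Entrez 8710) was at 984 ± 967 normalised counts in IBD, at least 1839-fold higher, SERPINB3 (6317) at 762 ± 1087, at least 1425-fold higher, and SERPINB4 (6318) at 268 ± 280, at least 502-fold higher. Without IBD replicate 5 these floors were 1261-fold, 528-fold and 300-fold. In IBD replicate 3 the 3 genes were only at 3.41, 7.67 and 9.38 normalised counts. SERPINB3 and SERPINB4 are close paralogs whose reads can be shared. SLCO1B3 (28234), an organic anion transporter best known from liver, rose from 1.23 ± 1.47 to 333 ± 183 (log2 change 7.21 ± 0.62, adjusted p = 5.25e-04). The neuropeptide S receptor NPSR1 (387129) rose from 1.25 ± 0.908 to 335 ± 154. The B cell chemokine CXCL13 (10563) rose by 6.82 ± 0.66, the acute phase protein SAA2 (6289) by 6.73 ± 0.91 and the Paneth cell defensin DEFA5 (1670) by 6.70 ± 1.57. DEFA5 did not rise in every donor: IBD replicate 4 held 9.38 normalised counts, below the 14.3 of control replicate 5. The pore-forming claudin CLDN2 (9075) rose from 9.84 ± 10.1 to 706 ± 368. The matrix protease MMP7 (4316) rose by 6.52 ± 0.72, the myeloid receptor CD300E (342510) by 6.44 ± 1.26, and DUOXA2 (405753), which matures the peroxide-forming oxidase DUOX2, by 6.39 ± 0.97.

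The largest fall on that scale was in CLDN8 (9073), a sealing claudin of the distal colon, from 6239 ± 4104 to 86.4 ± 142 (log2 change −7.20 ± 0.88, adjusted p = 0.00138). The amino acid transporter SLC6A19 (340024) fell from 1441 ± 793 to 13.8 ± 10.8, the glucuronidating enzyme UGT2A3 (79799) from 2448 ± 1208 to 50.2 ± 66.7 and the water channel AQP8 (343) from 20627 ± 18003 to 731 ± 1057. AQP8 overlapped between the groups, at 2477 in IBD replicate 3 and 2121 in control replicate 2. HOXD10 (3236) and HOXD11 (3237), homeobox genes of the posterior body, had changes of −5.92 ± 1.12 and −5.80 ± 0.90. The synaptic gene RIMS4 (140730) fell by 6.92, the potassium channel partner DPP10 (57628) by 6.79, the sialyltransferase ST6GAL2 (84620) by 6.18, the actin nucleator FMN2 (56776) by 6.18, KRTAP13-2 (337959) by 6.13, and the RNA-binding protein RBM24 (221662) had a change of −5.81 ± 1.06. All 24 of these genes stayed past the threshold when any 1 library was left out. With the pan-epithelial score as a covariate 17 did, and DEFA5 (7.27 ± 2.26), CD300E (4.49 ± 1.60), ST6GAL2 (−4.72 ± 1.37), AQP8 (−5.54 ± 1.92), HOXD10 (−5.26 ± 1.60), HOXD11 (−4.47 ± 1.17) and RBM24 (−5.84 ± 1.54) did not. The SE of each of these 7 was larger with the covariate than without it. AQP8 also missed it without both libraries rich in mitochondrial rRNA (−5.61). Within the libraries with size factors above 1, 10 of the 24 passed, and 16 within those below 1. The labels give no colon segment, and the distal colon genes PRAC1 (−1.66), PRAC2 (−1.50) and HOXB13 (−2.52) were also called lower. A difference in sampling site between the groups could therefore enter the falls of CLDN8 and the other genes.

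**Figure D1:**
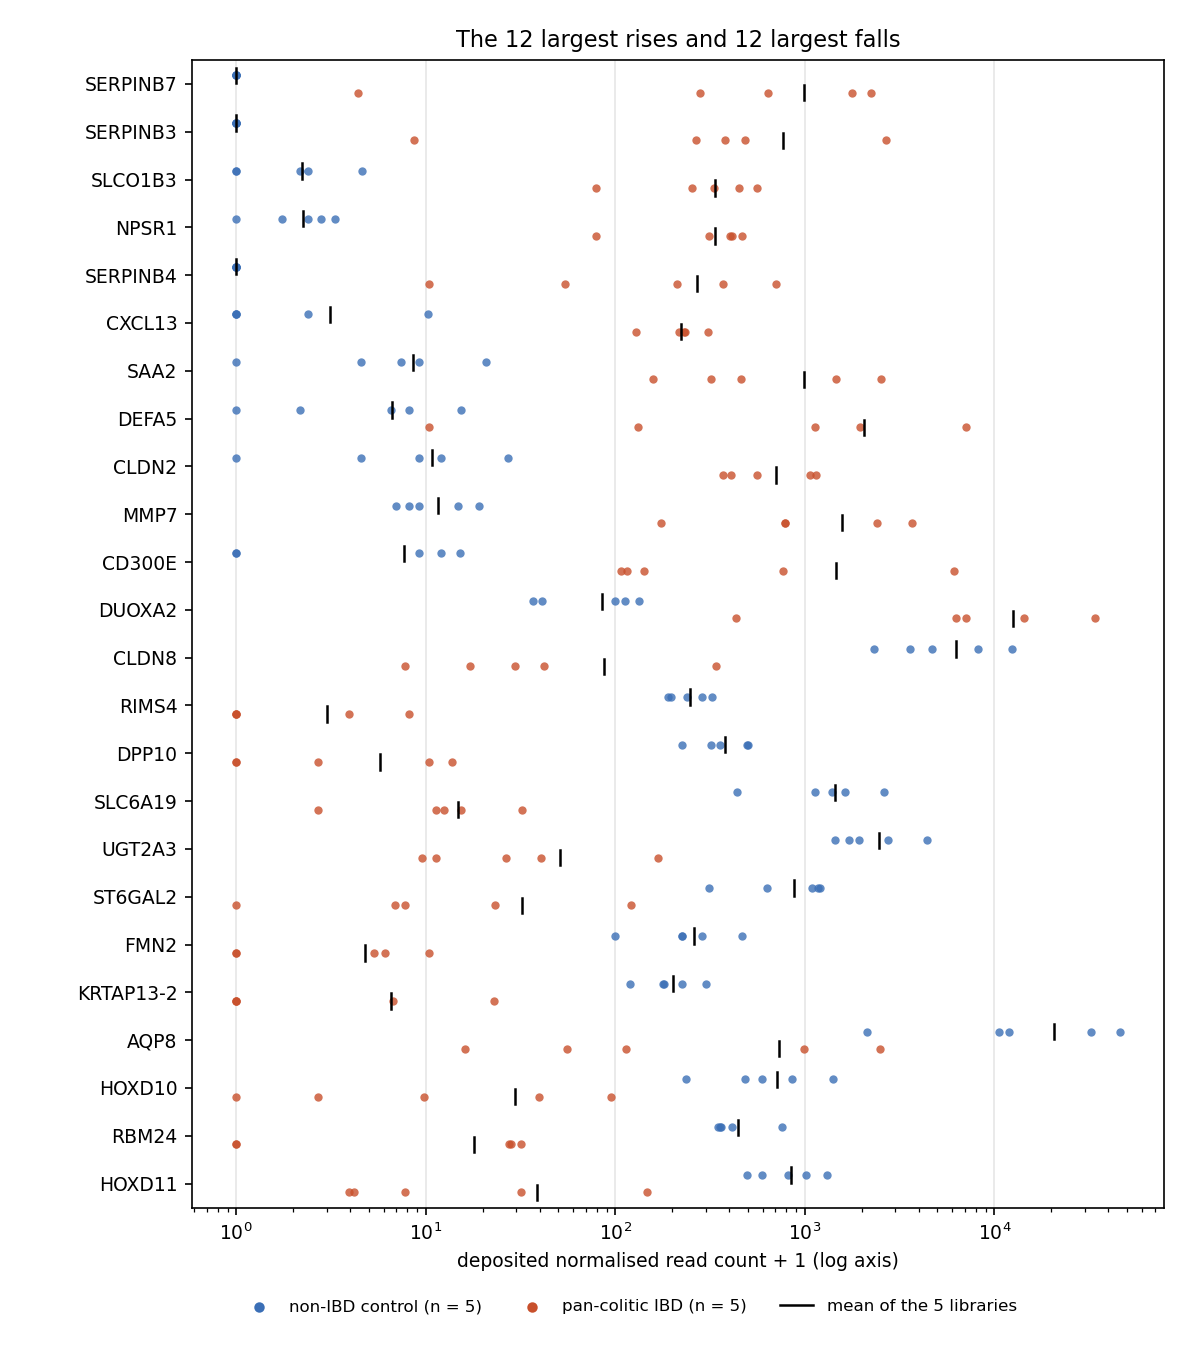
Deposited normalised read counts plus 1 (log axis) of the 12 largest rises and the 12 largest falls; each point is 1 library, blue for the 5 controls and red for the 5 IBD donors, and the black line is the mean of the 5. CLDN8 lies at a mean of 6239 in controls and 86.4 in IBD, and SLCO1B3 at 1.23 and 333.

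The number of changed genes was lower by over 1.5 times without some single libraries. It was 2269 without control replicate 1, 2159 without control replicate 3, 1900 without control replicate 5 and 2274 without IBD replicate 5. Genes higher then numbered 1183, 1138, 1044 and 1196, and genes lower 1086, 1021, 856 and 1078. Within the libraries with size factors above 1, 75 genes were called, and 834 within those below 1. All 3632 genes kept their direction within both classes. They were chosen by their difference over these same libraries, which largely fixes their direction, so this gives no separate support. Scaling to equal column totals gave 2069 genes, the pan-epithelial covariate 967 and leaving out both libraries rich in mitochondrial rRNA 2070. With the pan-epithelial covariate 632 of the 3632 calls were kept, so a lost call under it was the common outcome for any gene. Quasi-likelihood tests on the recovered reads (edgeR) called 3442 genes and DESeq2 called 5314. Of the 133 called genes chosen by size, by p within a list or in advance, 108 stayed called without any 1 library.

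The series title places these libraries in a study of dietary fibre, intestinal inflammation and group 2 innate lymphoid cells (ILC2), so the genes of that circuit were examined as a list. IL33 (90865), the alarmin that activates ILC2, rose from 266 ± 119 to 841 ± 399 (log2 change 1.66 ± 0.38, adjusted p = 0.0151). IL2RA (3559), a receptor chain of activated lymphocytes, rose by 2.78 ± 0.64 and IL1RAP (3556), the shared chain of the IL-33 and IL-1 receptors, by 2.10 ± 0.53. These 3 were the called members among 18 tested, and 0 fell; 3 rose when adjusted over the list alone. The IL-25 receptor IL17RB (55540) was at −0.79 ± 0.28 (adjusted p = 0.0676) and passed without control replicate 1 (−0.98) or IBD replicate 1 (−0.95), under quantile normalisation (−0.97) and in DESeq2 (−0.77). IL1RAP missed the threshold without control replicate 1 (2.02) or control replicate 3 (2.07). IL33 did so under equal column totals (1.57), with the pan-epithelial covariate (0.83) and among libraries with size factors above 1 (1.60). IL2RA and IL1RAP also missed it with the pan-epithelial covariate (1.41 and 1.97) and above 1 (1.87 and 0.86), and IL1RAP below 1 (2.96) and without both libraries rich in mitochondrial rRNA (1.805). The type 2 cytokines themselves were not separated from the spread. IL13 (3596) differed by 0.75 ± 1.10 (adjusted p = 0.654), with −1.03 among libraries with size factors above 1 and 2.72 among those below. IL5 (3567) differed by 1.47 ± 1.25 (adjusted p = 0.42), with −0.60 and 2.98 in the same classes. Without IBD replicate 5 these were at 0.0151 and 0.34, and over all single libraries left out they reached 1.32 and 2.17. The IL-33 receptor IL1RL1 (9173) differed by −0.35 ± 0.63 and the ILC2 regulator GATA3 (2625) by 0.79 ± 0.43. The tissue repair factor AREG (374) was at −0.80 ± 0.30 (adjusted p = 0.0830) and passed without control replicate 5 (−1.02) or IBD replicate 5 (−0.99), with array weights (−1.03) and in DESeq2 (−0.80). The list as a whole did not pass (median 0.49, adjusted p = 0.197; 0.16 to 0.73 when single libraries were left out), and among the alternatives it passed only in the class of size factors below 1 (0.81), against −0.07 in the class above 1. Mast cell and basophil genes showed no called member among 11 (0 rose and 0 fell, also when adjusted over the list alone), at a median of −0.24 (adjusted p = 0.699). That list passed in the class above 1 (−1.44). The histamine enzyme HDC differed by 0.75 ± 0.87 and the stem cell factor receptor KIT by 0.52 ± 0.48.

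Genes of eosinophils and their recruitment were higher in IBD. Of 12 tested members 4 rose, 0 fell and 8 did not pass (7 rose when adjusted over the list alone), with a median of 2.22 (adjusted p = 0.00120; adjusted p = 0.394 with an estimated correlation). CCL24 (6369), an eosinophil-attracting chemokine, rose from 65.3 ± 46.9 to 756 ± 272 (3.78 ± 0.51, adjusted p = 0.00228). CLC (1178), a granule protein of eosinophils, rose from 3.34 ± 3.33 to 56.6 ± 65.5 (3.74 ± 0.81). ADGRE1 rose by 3.68 ± 1.06 and the shared cytokine receptor chain CSF2RB by 2.23 ± 0.71. ADGRE1 missed the threshold without control replicate 1, 3 or 5 or IBD replicate 1, 4 or 5 (3.15 to 3.84), and CSF2RB without control replicate 1, 3 or 5 or IBD replicate 2, 3, 4 or 5 (1.77 to 2.43). Another eosinophil chemokine, CCL11 (6356), was at 27.0 ± 42.0 and 939 ± 1781 (4.32 ± 1.55, adjusted p = 0.0715) and passed without control replicate 4 (5.17) or IBD replicate 2 (5.26), under quantile normalisation (4.23) and with the size-factor class as a covariate (5.18). The pan-epithelial covariate left it at 0.92. IBD replicate 3 held 4119 normalised counts of CCL11, against 12.7 to 341 in the other IBD libraries, and without it the change was 3.21. CCL26 (10344) differed by 0.15 ± 0.73. CCL24 missed the threshold in the class of size factors above 1 (3.65), and CLC in both classes (3.15 and 4.19) and with the pan-epithelial covariate (4.40). The list missed the threshold among libraries with size factors above 1 (median 1.23), and 1 of its 4 called genes kept its call with the pan-epithelial covariate.

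**Figure D2:**
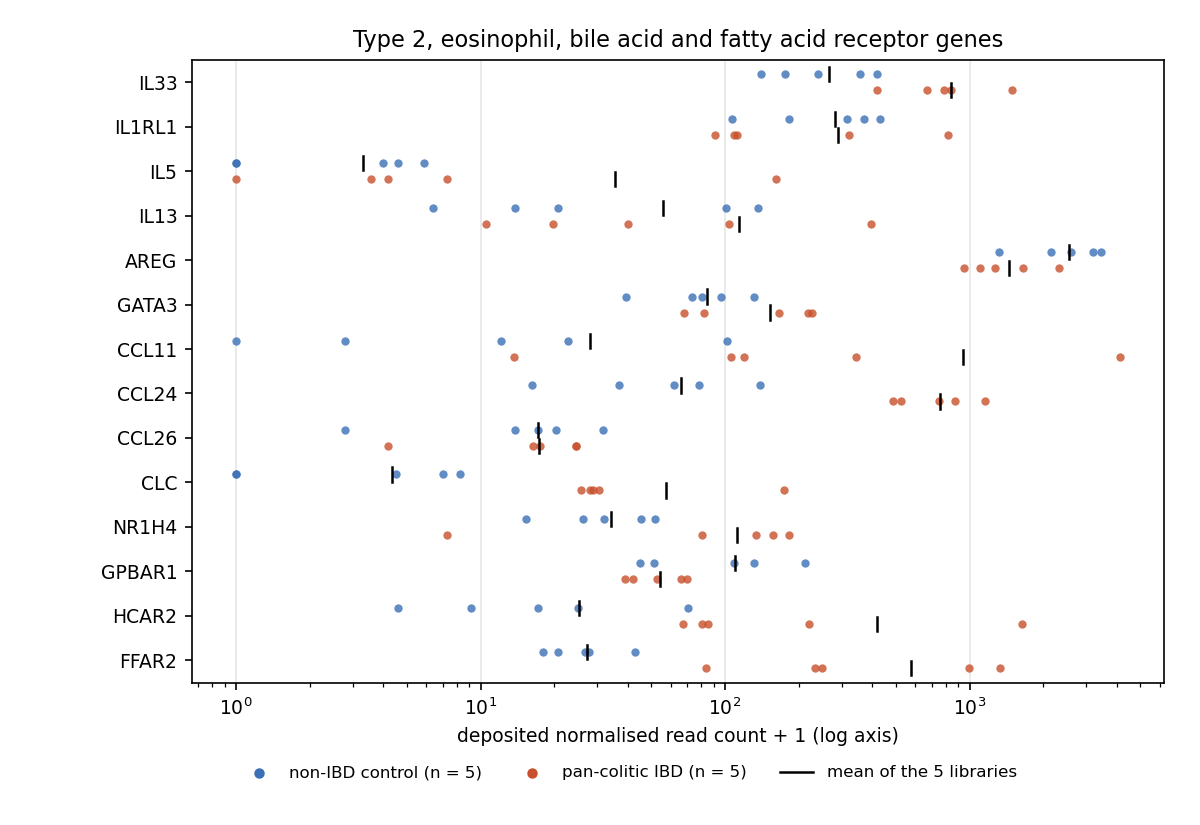
Deposited normalised read counts plus 1 (log axis) of the type 2, eosinophil, bile acid and fatty acid receptor genes chosen before the data were examined; each point is 1 library, blue for the 5 controls and red for the 5 IBD donors, and the black line is the mean of the 5. CCL24 and FFAR2 do not overlap between groups (means of 65.3 and 756, and of 26.2 and 577), while IL13 does (means of 54.6 and 113).

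Bile acid receptors, transporters and targets were lower in IBD. Of 17 tested members 0 rose, 5 fell and 12 did not pass (6 fell when adjusted over the list alone), at a median of −0.86 (adjusted p = 0.00682; adjusted p = 0.279 with an estimated correlation). CYP27A1, an enzyme of the acidic pathway of bile acid synthesis, fell from 1324 ± 529 to 309 ± 173 (−2.20 ± 0.40). VDR, the vitamin D receptor that also binds lithocholic acid, changed by −0.99 ± 0.24 and missed the threshold without control replicate 5 (−0.91). The xenobiotic receptor NR1I2 (−1.45 ± 0.41) missed it without control replicate 1, 3 or 5 or IBD replicate 1, 3 or 5 (−1.45 to −1.22). Of the 4 members of the list with the smallest p, 1 kept its call with the pan-epithelial covariate. The bile acid receptor NR1H4 (9971) was at 33.1 ± 14.7 and 111 ± 69.5 (1.24 ± 0.82, adjusted p = 0.298), and passed without IBD replicate 4 (2.08) and in DESeq2 (1.73). It was at 0.0461 with the pan-epithelial covariate. The membrane receptor GPBAR1 (151306) differed by −0.82 ± 0.44 (adjusted p = 0.198). FABP6, an ileal bile acid binding protein, was below the filter with 4 reads over the controls and 52 over IBD. Genes that sense, import and oxidise short-chain fatty acids went both ways: 2 rose, 5 fell and 7 of 14 did not pass (3 rose and 5 fell when adjusted over the list alone). Their median was −0.41 and their mean 0.05, so these differ in sign, and the test gave a fall that did not pass (adjusted p = 0.0647). It passed with the size-factor class as a covariate (median −0.43), in the class below 1 (−0.71), with a minimum mean of 50 (−0.49) and without control replicate 2 or 4 or IBD replicate 2 (−0.48 to −0.47). FFAR2 (2867), a short-chain fatty acid receptor also carried by neutrophils, rose from 26.2 ± 9.68 to 577 ± 551 (3.81 ± 0.68, adjusted p = 0.00614). It missed the threshold in the class above 1 (2.35) and with the pan-epithelial covariate (3.84). HCAR2 (338442), which binds butyrate, rose by 3.40 ± 0.96 and missed the threshold without control replicate 1, 3 or 5 or IBD replicate 4 (2.94 to 3.41). It also missed it with the pan-epithelial covariate (1.90), in the classes above and below 1 (1.59 and 5.12) and without both libraries rich in mitochondrial rRNA (3.22). ACADS and ACAT1, enzymes of butyrate oxidation, changed by −1.27 ± 0.27 and −1.24 ± 0.22. ACADS and ACAT1 also lost their calls with the pan-epithelial covariate.

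Antimicrobial and neutrophil genes had the highest medians of the lists, and inflammatory monocyte genes were also higher in IBD. Neutrophil genes and chemokines rose in 16 of 18 tested members, 0 fell and 2 did not pass (17 rose when adjusted over the list alone), at a median of 4.18 (adjusted p = 4.35e-11; adjusted p = 0.279 with an estimated correlation). The calprotectin subunits S100A8 and S100A9 rose from 11.2 ± 6.77 to 1678 ± 2378 (6.29 ± 0.79) and from 56.8 ± 24.7 to 7660 ± 9220 (6.28 ± 0.77). The formyl peptide receptor FPR1 rose by 5.15 ± 0.85 and the chemokine CXCL1 by 3.98 ± 0.64. Antimicrobial and inflamed-epithelium genes rose in 16 of 21, 0 fell and 5 did not pass (19 rose when adjusted over the list alone), at a median of 5.09 (adjusted p = 1.79e-10; adjusted p = 0.279 with an estimated correlation). DMBT1, a secreted scavenger protein, rose from 3466 ± 1655 to 178745 ± 146036 (5.27 ± 0.72), DUOX2 by 4.89 ± 0.71 and SAA1 by 6.05 ± 0.85. SAA1 and SAA2 are near-identical copies that can share reads. Inflammatory monocyte and macrophage genes rose in 9 of 19, 0 fell and 10 did not pass (14 rose when adjusted over the list alone), at a median of 2.63 (adjusted p = 5.45e-07; adjusted p = 0.394 with an estimated correlation). TREM1, an amplifying receptor of myeloid cells, rose by 6.10 ± 1.02, the monocyte lectin FCN1 by 5.79 ± 1.08 and the cytokine OSM by 3.13 ± 0.67. With the pan-epithelial covariate, 3 of the 4 named neutrophil genes, 4 of the 4 named antimicrobial genes and 0 of the 4 named monocyte genes kept their call. Of all 3632 called genes 632 did.

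Interferon-induced genes and class II antigen presentation rose together in IBD. Of 20 interferon response genes 16 rose, 0 fell and 4 did not pass (17 rose when adjusted over the list alone), at a median of 2.96 (adjusted p = 3.54e-12; adjusted p = 0.279 with an estimated correlation). IDO1, which degrades tryptophan, rose from 84.5 ± 44.0 to 4179 ± 1969 (5.51 ± 0.54, adjusted p = 6.63e-04). The chemokine CXCL11 rose by 5.42 ± 0.57 and the guanylate-binding protein GBP4 by 3.26 ± 0.37. Of 10 class II genes 9 rose, 0 fell and 1 did not pass (9 rose when adjusted over the list alone), at a median of 2.65 (adjusted p = 3.83e-07; adjusted p = 0.279 with an estimated correlation). The class II transactivator CIITA rose by 2.73 ± 0.30, the invariant chain CD74 by 2.49 ± 0.38 and the peptide exchange chains HLA-DMB and HLA-DOA by 2.40 ± 0.32 and 2.68 ± 0.41. Of the members with the smallest p, 4 of 4 in each list kept their call with the pan-epithelial covariate.

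Lymphocyte genes rose across T, cytotoxic, B and plasma cell lists. T cell genes rose in 9 of 16, 0 fell and 7 did not pass (12 rose when adjusted over the list alone), at a median of 1.53 (adjusted p = 3.69e-07; adjusted p = 0.394 with an estimated correlation). The checkpoint receptor CTLA4 rose from 89.6 ± 41.1 to 1104 ± 389 (3.69 ± 0.36), FOXP3, the regulatory T cell factor, by 3.18 ± 0.58 and the kinase LCK by 1.51 ± 0.28. Cytotoxic lymphocyte genes rose in 8 of 14, 0 fell and 6 did not pass (10 rose when adjusted over the list alone), at a median of 1.75 (adjusted p = 2.09e-05; adjusted p = 0.394 with an estimated correlation). Granzyme B (GZMB) rose by 4.14 ± 0.77 and perforin (PRF1) by 2.63 ± 0.46. Genes of the Th17 and ILC3 axis rose in 5 of 13, 0 fell and 8 did not pass (5 rose and 1 fell when adjusted over the list alone), at a median of 1.384 (adjusted p = 0.0130; adjusted p = 0.394 with an estimated correlation). IL17A rose from 16.9 ± 11.1 to 353 ± 369 (3.86 ± 0.75) and IL26 from 2.19 ± 2.92 to 50.1 ± 21.7 (4.40 ± 0.67). The Th17 list missed the threshold among libraries with size factors above 1 (median 0.78) and with a minimum mean of 50 (0.69). Its median was 0.88 without control replicate 1 and still passed. B cell and follicle genes rose in 12 of 16, 0 fell and 4 did not pass (15 rose when adjusted over the list alone), at a median of 1.83 (adjusted p = 2.03e-08; adjusted p = 0.279 with an estimated correlation). The B cell receptor chain CD79B rose by 2.33 ± 0.39. Plasma cell genes rose in 5 of 16, 0 fell and 11 did not pass (11 rose when adjusted over the list alone), at a median of 1.84 (adjusted p = 2.09e-05; adjusted p = 0.42 with an estimated correlation). The immunoglobulin G heavy chain IGHG1 rose from 18456 ± 15099 to 1838040 ± 1781790 (6.35 ± 0.86), while IGHA1, the heavy chain of immunoglobulin A, was at 315351 ± 395428 and 553833 ± 346332 (1.70 ± 1.06, adjusted p = 0.269; named after its values were seen). With the pan-epithelial covariate, 1 of the 4 named T cell genes, 0 of 4 cytotoxic, 1 of 4 Th17, 2 of 4 B cell and 2 of 4 plasma cell genes kept their call.

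Mature absorptive colonocyte genes and pan-epithelial genes were lower in IBD. Of 20 colonocyte genes 15 fell, 0 rose and 5 did not pass (15 fell when adjusted over the list alone), at a median of −2.57 (adjusted p = 3.83e-07; adjusted p = 0.394 with an estimated correlation). The sulphate transporter SLC26A2 fell from 173085 ± 142514 to 4180 ± 2886 (−5.24 ± 0.62), the magnesium channel TRPM6 changed by −3.66 ± 0.71 and the guanylate cyclase ligand GUCA2B by −3.41 ± 0.65. Pan-epithelial genes fell in 7 of 15, 0 rose and 8 did not pass (7 fell when adjusted over the list alone), at a median of −0.77 (adjusted p = 8.88e-05; adjusted p = 0.42 with an estimated correlation). The claudins CLDN4 and CLDN3 changed by −1.59 ± 0.32 and −1.33 ± 0.26 and the intestinal factor CDX2 by −1.12 ± 0.26. The colonocyte score less the pan-epithelial score differed by −1.54 (95% interval −2.80 to −0.27, exact permutation p = 0.0476), a test written after the lists had been seen. Tight junction genes split, with 2 rising, 4 falling and 8 of 14 not passing (2 rose and 5 fell when adjusted over the list alone), at a median of −0.72 (adjusted p = 0.00830; adjusted p = 0.42 with an estimated correlation). CLDN2 and CLDN1 rose by 6.55 ± 0.78 and 3.74 ± 0.56, and CLDN8 and CLDN23 changed by −7.20 ± 0.88 and −2.52 ± 0.29. With the pan-epithelial covariate, 1 of the 4 named colonocyte genes and 4 of 4 tight junction genes kept their call. The median of the tight junction list went to 0.0018 with it and missed the threshold. The covariate is the mean of the pan-epithelial list and takes out the mean change of that list by construction. That 0 of its 4 named genes kept their call is therefore no result.

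The goblet, stem, enteroendocrine and tuft cell lists did not pass the main test, and 3 of them passed under some alternatives. Goblet cell genes had 2 rises, 1 fall and 13 of 16 not passing (2 rose and 2 fell when adjusted over the list alone; median 0.25, adjusted p = 0.831). The list passed with the pan-epithelial covariate (1.14). SPINK4, a goblet cell protease inhibitor, rose from 279 ± 145 to 6800 ± 4917 (4.44 ± 0.47), and the secreted protein WFDC2 changed by −2.49 ± 0.56. Stem and transit-amplifying genes had 2 rises, 2 falls and 8 of 12 not passing (2 rose and 3 fell when adjusted over the list alone), with a median of −0.10, a mean of 0.11 and a test direction of a fall (adjusted p = 0.614). OLFM4, a crypt base glycoprotein, rose from 4990 ± 4927 to 161308 ± 155924 (5.24 ± 0.77). PTPRO and AXIN2 fell by 1.65 ± 0.47 and by 0.99 ± 0.32 and missed the threshold without most single libraries. SMOC2 rose by 1.94 ± 0.50 and missed the threshold without control replicate 5 (1.97). Enteroendocrine genes had 1 rise, 3 falls and 9 of 13 not passing (1 rose and 3 fell when adjusted over the list alone; median −0.998, adjusted p = 0.114), with NEUROD1, a factor of hormone cells, at −1.72 ± 0.40. That list passed with array weights (−1.21), without control replicate 1 (−1.25), without both libraries rich in mitochondrial rRNA (−1.12) and in the class above 1 (−1.07). Tuft cell genes had 4 rises, 0 falls and 8 of 12 not passing (4 rose when adjusted over the list alone; median 0.41, adjusted p = 0.106). They passed with the pan-epithelial covariate (0.89), under equal column totals (0.33) and without IBD replicate 3 (0.70). Among the tuft cell members that rose, ALOX5 (1.99 ± 0.47) and LRMP (1.75 ± 0.41) are also genes of leukocytes. Cell cycle genes rose in 5 of 16, 0 fell and 11 did not pass (8 rose when adjusted over the list alone), at a median of 0.94 (adjusted p = 7.32e-05; adjusted p = 0.42 with an estimated correlation). The ribonucleotide reductase RRM2 rose by 1.94 ± 0.50 and missed the threshold without control replicate 5 (1.82) or IBD replicate 1 (1.77). Cyclin B1 (CCNB1) rose by 1.33 ± 0.34 and missed it without control replicate 5 (1.21). Of the 4 cell cycle genes with the smallest p, 0 kept their call through every removal of 1 library. Of the called genes among the 4 named in each list, 1 of 3 goblet, 1 of 4 stem and 0 of 4 enteroendocrine, tuft and cell cycle genes kept their call with the pan-epithelial covariate.

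The endothelial, fibroblast and smooth muscle lists were higher in IBD by camera at the preset correlation, and of these fry passed the endothelial list only. Endothelial and leukocyte adhesion genes rose in 10 of 14, 0 fell and 4 did not pass (11 rose when adjusted over the list alone), at a median of 2.34 (adjusted p = 4.02e-06; adjusted p = 0.394 with an estimated correlation). P-selectin (SELP) rose from 125 ± 97.3 to 1510 ± 1007 (3.78 ± 0.73), and the vessel markers VWF and PECAM1 by 2.55 ± 0.50 and 2.82 ± 0.59. Fibroblast and matrix genes rose in 4 of 18, 0 fell and 14 did not pass (6 rose when adjusted over the list alone), at a median of 1.44 (adjusted p = 0.00293; adjusted p = 0.486 with an estimated correlation). Without control replicate 1 that list was at 0.88 and still passed. The collagenase MMP1 and the stromelysin MMP3 rose by 5.32 ± 1.07 and 5.83 ± 0.78, FAP, a marker of activated fibroblasts, by 3.06 ± 0.74 and the protease inhibitor TIMP1 by 3.04 ± 0.70. Smooth muscle and pericyte genes had 1 rise, 0 falls and 10 of 11 not passing (0 when adjusted over the list alone), at a median of 0.94 (adjusted p = 0.0363; adjusted p = 0.547 with an estimated correlation). That 1 rise is near the share of all tested genes that rose (1901 of 18235). The pericyte gene RGS5 was at 2.66 ± 0.79. It kept its call without control replicate 4 (3.02) or IBD replicate 2 (3.32) and missed the threshold without any other library (2.02 to 2.75). The smooth muscle list missed it without control replicate 1, control replicate 5, IBD replicate 1 or IBD replicate 3 (0.59 to 0.93), and with a minimum mean of 50. Enteric glia and neuron genes had 2 rises, 0 falls and 8 of 10 not passing (2 rose when adjusted over the list alone; median 1.35, adjusted p = 0.0817), with the glial protein S100B at 4.14 ± 0.89 and the tubulin TUBB3 at 1.70 ± 0.39. Red blood cell and platelet genes had 1 rise, 1 fall and 3 of 5 not passing (2 rose and 1 fell when adjusted over the list alone; median 0.24, adjusted p = 0.858). With the pan-epithelial covariate 0 of the 4 named endothelial genes and 1 of the 4 named fibroblast genes kept their call, and the medians of the fibroblast and smooth muscle lists were −0.60 and −0.56.

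Mitochondrial genes were lower and secretory stress genes higher in IBD. Nuclear-encoded genes of mitochondrial respiration fell in 7 of 20, 0 rose and 13 did not pass (13 fell when adjusted over the list alone), at a median of −0.46 (adjusted p = 4.77e-06; adjusted p = 0.394 with an estimated correlation). PPARGC1A and PPARGC1B, regulators of mitochondrial biogenesis, changed by −2.60 ± 0.40 and −1.46 ± 0.30 and the complex I subunit NDUFV1 by −0.57 ± 0.11. Mitochondrially encoded transcripts fell in 2 of 11, 0 rose and 9 did not pass (7 fell when adjusted over the list alone), at a median of −1.35 (adjusted p = 4.76e-04; adjusted p = 0.422 with an estimated correlation). Mitochondrial mRNA took 16.9% of reads in control replicate 5 and 6.13% to 8.35% in the other controls, and without that library the list still passed, at a median of −0.99. MT-ND1 was at −1.41 ± 0.37 and missed the threshold without control replicate 1 (−1.37) or IBD replicate 3 (−1.29). Genes of the unfolded protein response rose in 7 of 16, 1 fell and 8 did not pass (12 rose and 1 fell when adjusted over the list alone), at a median of 0.94 (adjusted p = 2.05e-04; adjusted p = 0.42 with an estimated correlation). The protein disulphide isomerase PDIA4 rose by 1.22 ± 0.23 and EDEM1, which sorts misfolded proteins for degradation, by 1.03 ± 0.21, while the stress factor DDIT3 changed by −0.94 ± 0.20. Genes induced by tissue dissociation and heat fell in 3 of 16, 0 rose and 13 did not pass (3 fell when adjusted over the list alone), at a median of −0.96 (adjusted p = 4.76e-04; adjusted p = 0.427 with an estimated correlation). The immediate early genes EGR1, FOS and IER2 changed by −1.46 ± 0.21, −0.98 ± 0.21 and −0.96 ± 0.16. Ribosomal protein genes, a reference for RNA quality, had 0 called members of 16 (0 when adjusted over the list alone) and a median of 0.12 (adjusted p = 0.699). With the pan-epithelial covariate the respiration and unfolded protein response lists missed the threshold (medians −0.13 and 0.57).

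**Figure D3:**
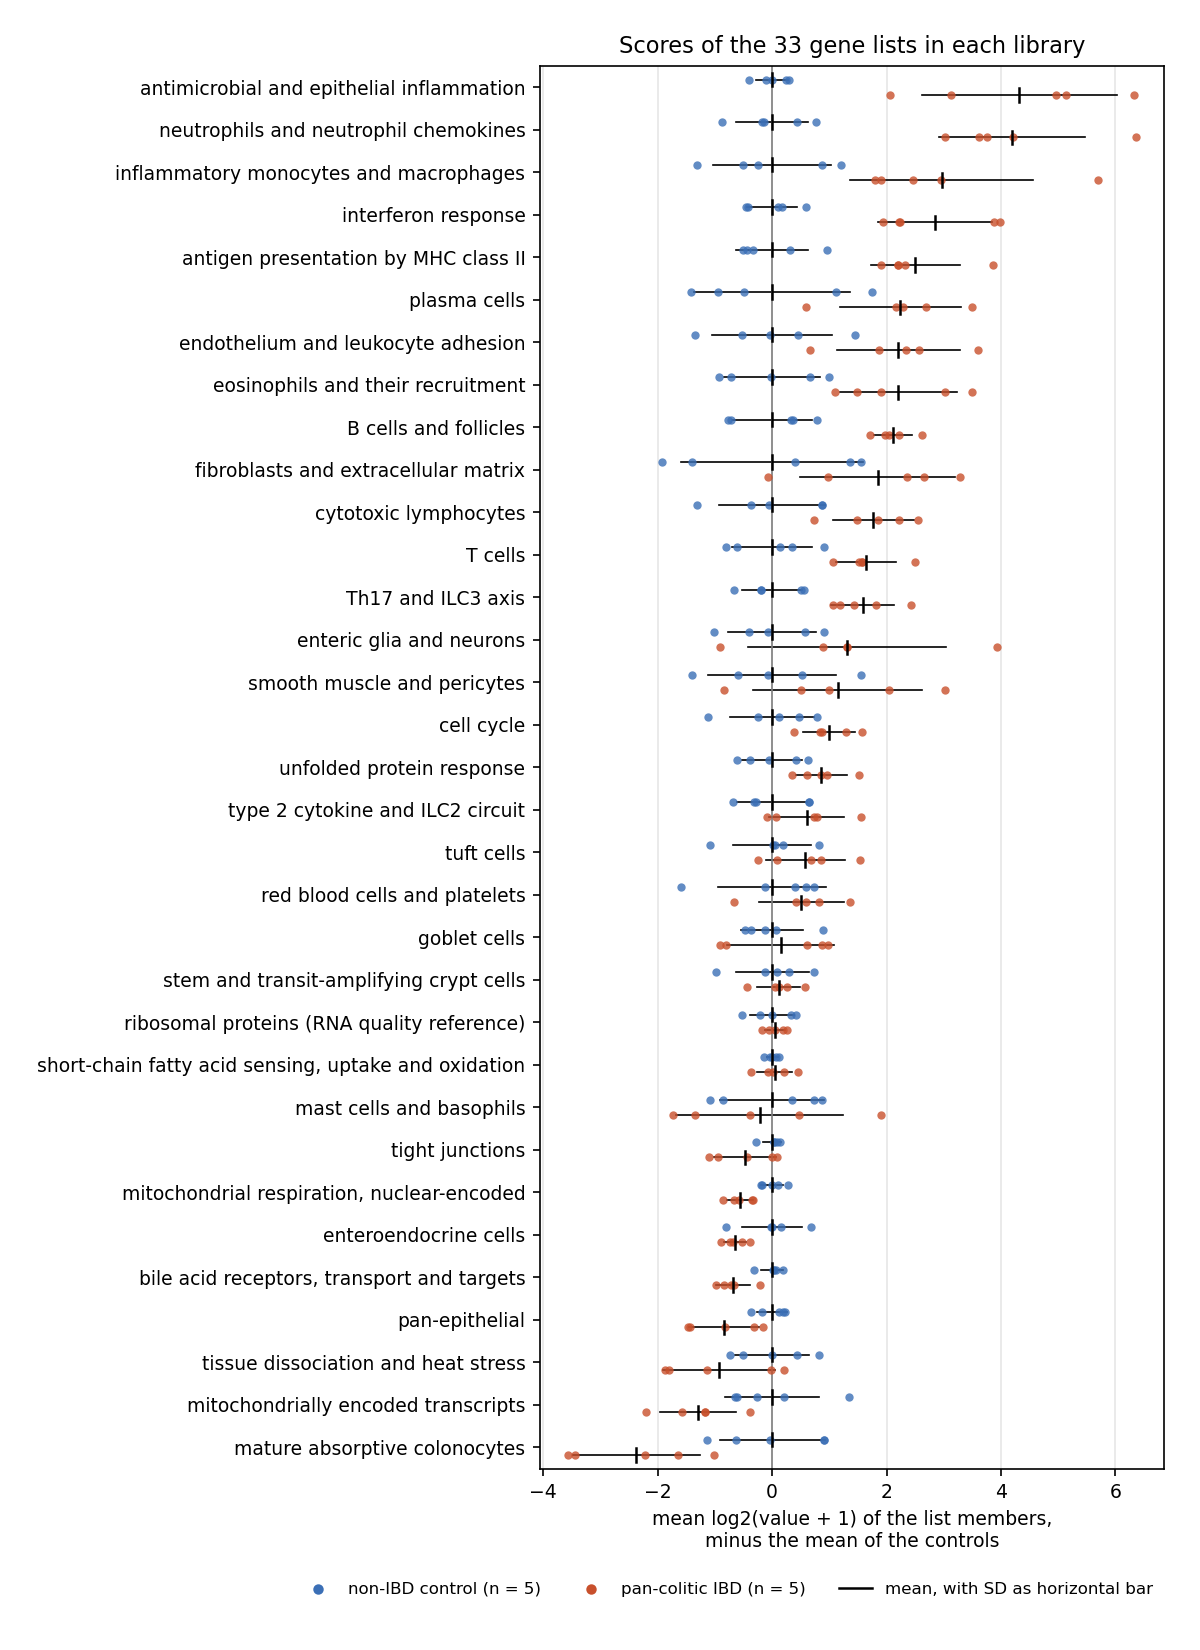
Score of each of the 33 gene lists in each library, as the mean log2(value + 1) of its members less the mean of the controls; each point is 1 library, blue for the 5 controls and red for the 5 IBD donors, the black tick is the group mean and the horizontal bar the SD. The neutrophil score differs by 4.19 and the colonocyte score by −2.38, and 10 of the 33 lists show no overlap between groups.

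Of the 33 lists, 23 passed with the preset correlation, 16 higher and 7 lower in IBD. In the other divisions of the libraries refitted below, which mix the groups, 3 to 25 lists passed at this correlation. Its p-values therefore do not measure the spread between donors. With an estimated correlation camera passed 0, with adjusted p from 0.279 to 0.930 and 5 lists at an unadjusted p under 0.05. The directional test of fry, which asks whether the genes of a list move one way without comparing them with other genes, passed 20 lists. The number of lists that passed was 19 to 26 over the alternatives other than edgeR and DESeq2, in which lists were not tested.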

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

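The values below were found by a rule set in advance that looks for 1 library far from the other 4 of its group, and no explanation was tested for them. It found 8 cases in 155 groups of 5 values (5.16%), and chance gives about 1 in 20. Mitochondrial mRNA took 16.9% of reads in control replicate 5, against 6.13% to 8.35% in the other controls. The class II antigen presentation score was 12.4 in IBD replicate 5, against 10.4 to 10.9 in the other IBD libraries. The tight junction score was 10.47 in control replicate 2, against 10.8 to 10.9 in the other controls. On the log2 scale, NPSR1 was at 6.30 in IBD replicate 2, against 8.29 to 8.87 in the other IBD libraries. RBM24 was at 9.56 in control replicate 1, against 8.44 to 8.68 in the other controls. CCL26 was at 2.06 in IBD replicate 2, against 4.03 to 4.62. CLC was at 7.45 in IBD replicate 4, against 4.68 to 4.93. NR1H4 was at 2.86 in IBD replicate 4, against 6.33 to 7.51.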

How the results depend on the processing

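Among these settings the size-factor class as a covariate, each class alone and the fit without the libraries rich in mitochondrial rRNA were chosen after the data were seen. All 3632 called genes kept their direction in every setting that tested them (3315 of 3315 at a minimum mean of 50). Every setting reuses the libraries in which these genes were called, which largely fixes their direction, so this is no separate evidence. Over 25 settings the named genes gave 4036 values, of which 3492 kept direction and side of the threshold, 471 lost the call, 55 gained it and 18 changed sign. Lists were tested in 23 of these settings, not in edgeR or DESeq2, and their 758 values split into 699, 10, 25 and 24. None of the sign changes was in a called gene, which follows largely from calling the genes on the same libraries. Genes changed, higher and lower were 2069, 939 and 1130 under equal column totals, 967, 443 and 524 with the pan-epithelial covariate, 2070, 1153 and 917 without both libraries rich in mitochondrial rRNA, 75, 44 and 31 in the class of size factors above 1, and 834, 491 and 343 in the class below 1. Fewer libraries enter the last 3. DESeq2 called 2880 higher genes. Leaving out single libraries gave 1900 to 3630 changed, 1044 to 1956 higher and 856 to 1684 lower genes. The lists that passed numbered 19 to 26. The enteric glia and neuron list, which had not passed, did so in 8 settings (medians 0.69 to 2.34), and the ribosomal list among size factors below 1 (0.38).

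Under the pan-epithelial covariate the changes of ACTA2 (−0.56), IL5 (−0.19), IL13 (−1.41) and CCL26 (−0.99) took the other sign. So did the medians of the type 2 (−0.10), pan-epithelial (0.17), stem cell (0.0435), fibroblast (−0.60), smooth muscle (−0.56), glia (−0.94), red blood cell (−1.16), tight junction (0.0018) and ribosomal (−0.0892) lists, of which the pan-epithelial, fibroblast, smooth muscle and tight junction lists had passed. The covariate removes the mean change of the pan-epithelial list by construction, so the value of that list is no result. With array weights the signs of CCL26 (−0.0273) and the red blood cell list (−0.80) changed, in edgeR that of IL1RL1 (0.0397), and in DESeq2 those of IL1RL1 (0.0427) and CCL26 (−0.0017). Without both libraries rich in mitochondrial rRNA the red blood cell (−0.72) and ribosomal (−0.0271) lists changed sign. Among size factors above 1, KIT (−0.38), HDC (−1.44), IL5 (−0.60), IL13 (−1.03), CCL26 (−0.29) and the type 2 (−0.0654), red blood cell (−1.17) and ribosomal (−0.0100) lists did. Among those below 1, MS4A2 (0.0705), IL1RL1 (0.24) and the mast cell (0.24), goblet cell (−0.37) and stem cell (0.0471) lists did. Leaving out single libraries gave −0.41 to 0.61 for CCL26, and medians of −0.68 to 0.93 for the red blood cell, −0.0056 to 0.23 for the ribosomal, −0.32 to 0.0259 for the stem cell and −0.85 to 0.0255 for the mast cell list. Other medians kept their sign but moved by over 1.5 times, among them those of the glia (0.77 to 1.65), enteroendocrine (−1.25 to −0.63), goblet cell (0.0547 to 0.50) and tuft cell (0.0502 to 0.77) lists. The cause of these changes was not tested. Of the genes changed 2-fold in simulated data, 10% were recovered. Only 200 genes were changed there, which makes the adjusted threshold stricter than in these data, so this share is not their sensitivity. A gene that did not pass can still have changed 2-fold.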

Other observations

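The gene families below, the 3 patterns, the test of colonocyte against pan-epithelial genes and the size-factor class as a covariate were chosen after the data were seen. Fisher's exact test counts the genes of a family as independent, while such genes can vary together across donors and share reads. Correlation within families was not allowed for, so the adjusted p of each family below does not measure variation between donors. Metallothioneins, small proteins that bind zinc and copper, were lower in IBD. Of 9 family members tested 7 fell and 0 rose (median −2.79, adjusted p = 2.40e-04, Fisher's exact test against 15575 tested genes, without antisense genes and genes never named). MT1M fell from 1633 ± 1256 to 60.4 ± 75.6, MT1G from 3034 ± 1920 to 192 ± 174 and MT2A from 2508 ± 1517 to 737 ± 321. The copies are alike and can share reads. All 7 stayed called without any 1 library and with the pan-epithelial score as a covariate, and the family median was −2.79 with TMM, −2.82 with equal totals and −2.81 with quantile normalisation. UDP-glucuronosyltransferases, enzymes that make hormones, bilirubin and drugs soluble, fell in 6 of 14 members and rose in 0 (median −2.29, adjusted p = 0.0354). The 14 include UGT8, which shares the stem but adds galactose to ceramide (−0.60 ± 0.28, not called). UGT1A8 fell from 611 ± 516 to 115 ± 38.0 and UGT2B7 from 141 ± 43.1 to 43.4 ± 22.8. The genes of the UGT1A cluster share exons. Of the 6, 4 stayed called without any 1 library and 1 with the pan-epithelial covariate, where the family median was −1.76. That median was −2.28 to −2.32 with TMM and equal totals and −2.18 with quantile normalisation.

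Proteasome beta subunits rose in 8 of 10 members tested, and 0 fell (median 0.51, adjusted p = 1.22e-04). The largest changes were in the interferon-induced subunits of the immunoproteasome. PSMB9 rose from 62.6 ± 23.4 to 386 ± 85.6 (log2 change 2.69 ± 0.34), PSMB8 by 1.13 ± 0.19 and PSMB10 by 0.95 ± 0.19. The family median was 0.43 to 0.52 over the 3 other scalings, and of the 8, 5 stayed called without any 1 library and 4 with the pan-epithelial covariate, where the median was 0.52. Histone genes of the replication clusters, whose RNA rises in S phase, rose in 29 of 66 members and fell in 0 (median 0.84, adjusted p = 3.95e-09). HIST1H3J rose from 410 ± 176 to 1302 ± 281 and HIST1H3G from 763 ± 347 to 1887 ± 504. Their median was 0.75 to 0.85 over the other scalings, and of the 29, 11 stayed called without any 1 library and 0 with the pan-epithelial covariate (median 0.71). The B clade of serpins rose in 8 of 9 members and fell in 0 (median 3.29, adjusted p = 3.61e-05), with SERPINB5 rising from 421 ± 160 to 4449 ± 2596. Of those 8, 6 stayed called without any 1 library and 5 with the pan-epithelial covariate (median 2.45).

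HOXD10, HOXD11, HOXD12 and HOXD13 were lower in IBD at a median of −5.65. Lower epithelial content alone would have taken most of this fall away, yet with the pan-epithelial score as a covariate the median was −4.35. HOXD10 went from −5.92 ± 1.12 to −5.26 ± 1.60 and HOXD11 from −5.80 ± 0.90 to −4.47 ± 1.17. HOXD12 went from −4.98 ± 0.88 to −3.91 ± 1.19 and HOXD13 from −5.51 ± 1.04 to −4.23 ± 1.39. The calls of all 4 ended as the fold shrank and the SE grew. Biopsies from another segment of the colon could also lower these genes, and the distal colon genes PRAC1, PRAC2 and HOXB13, fixed before their values were seen, fell at a median of −1.66. The labels give no segment, so the sampling site stays open, as does the disease itself, which was not tested.

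Colonocyte genes fell at a median of −2.57. With the class of size factor as a covariate the median was −2.70 and 15 of the 15 called members stayed called. The fall thus does not come from an uneven split of the classes over the groups. That split was nearly even (3 controls and 2 IBD above 1, 2 controls and 3 IBD below 1). The covariate could therefore hardly shrink the fall, and this is a weak test of the class. A lower share of epithelium would move these genes like the pan-epithelial genes, and the colonocyte score less the pan-epithelial score differed by −1.54. That explanation stays open, since the 95% interval (−2.80 to −0.27) reaches differences too small to tell. A change in the maturity of the epithelium, the sampling site and the disease itself stay open, untested.

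IgG heavy chain genes rose far more than the IgA heavy chain. More plasma cells of every class would raise both alike, yet the log2 ratio of IGHG1 to IGHA1 was higher in IBD by 4.65 (95% half-width 1.73, exact permutation p = 0.00794, the smallest this design gives). Reads moved between the IGHG copies would leave their sum level. All 4 copies rose, IGHG1 by 6.35, IGHG2 by 4.43, IGHG3 by 6.29 and IGHG4 by 5.17, which argues against such a move. Their sum had to rise with them. The summed value was higher by 5.90 (95% half-width 2.23, exact permutation p = 0.00794), which adds no test beyond those rises. A shift of plasma cells toward IgG in IBD may account for these values and remains a hypothesis, since the donors and the sampling site were not separated from the disease.

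The number of changed genes was set against other divisions of the 10 libraries into 5 and 5, of which 100 of 126 were refitted. Only 1 of the 100, the real one, gave as many changed genes (3632, against 328 at the highest other). Chance is therefore unlikely, though 1 in 100 is the smallest share this test can give. The same held for genes higher (1 of 100; 1901 against 183) and lower (1 of 100; 1731 against 183), where each other division counted by the larger of its directions. For lists 8 of the 100 gave as many as the real 23, with 25 at the highest other, so chance cannot be excluded for the number of lists. These divisions do not separate the disease from donor traits or a sampling site that follow the groups.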
